A study of Rattus norvegicus with 4 samples.

How the data were processed

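Total RNA from cultured rat oligodendrocyte precursor cells (OPCs), the dividing cells that give rise to myelinating oligodendrocytes, was measured on 4 single-colour Agilent arrays. Per the labels' protocols, the cells came from cortex at postnatal day 2, grew for 3 days with bFGF and PDGF, and were transfected with a mimic of the microRNA miR-125a-3p or with a negative control RNA at 50 nM. RNA was taken 48 h later and 100 ng of it was labelled with Cy3. The labels put 2 samples in each group, called miR-neg and miR-125a-3p here, and the series' design text calls the samples of a condition independent without saying whether they came from separate animals or cultures, so p-values measure the spread between these samples. The purpose stated in the series' title was to measure expression after raising this microRNA.

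The scanner values were intensities, background-subtracted and detrended within each array by Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The deposited value table held log2 values. For 99.3% of its probes on each array it equalled, within 0.01, the log2 processed intensity minus 1 constant per array, and its 75th percentile lay at 0, so scale, centring and direction were settled from the data. Its column medians were -4.07 and -4.15 for miR-neg and -4.08 and -4.14 for miR-125a-3p.

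The values tested were computed from the scanner intensities. Control spots and spots flagged as outliers were left out, replicate spots of a probe were averaged on the log2 scale, and each array's 75th percentile was subtracted. Of 45598 probes, 27273 were kept because they were well above background on at least 2 arrays, and 65 probes were left out for flagged spots. RefSeq accessions were paired with current symbols through a table of the GRCr8 assembly, which named 21109 probes (46.3%). The other 24489 probes, among them 13212 for predicted RefSeq transcripts and 6958 for Ensembl transcripts, stayed in the fit under their own identifiers. Coordinates are not given, since the array design was made on another assembly. The probe with the highest mean over all 4 arrays stood for its gene, which left 23155 features, 11676 of them with a gene symbol.

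The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. An exact permutation test of 2 against 2 samples cannot give a p below 0.333, so limma's moderated test, which shares the spread across features, was used for every gene. Gene lists were tested with limma's camera at a preset correlation of 0.01 over the features with a symbol, adjusted over 23 lists, of which 1 is not reported here, as are a few single genes. Camera asks whether a list's genes lie higher or lower than other genes. It was repeated with an estimated correlation, and fry, which asks whether a list's genes move on balance in 1 direction, was also run. The repeat with an estimated correlation rests on the 2 residual degrees of freedom, where a call is hard to reach. A call lost there does not by itself show that correlation between genes undid it. The lists, the tests, the naming rule and most alternatives were fixed before the data were examined. The 5 target genes were listed from memory of the literature.

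The naming rule took the 10 largest increases and the 10 largest decreases among genes with a symbol that were past the threshold and well above background on all 4 arrays, with both miR-125a-3p arrays on the same side of both miR-neg arrays. It added up to 3 genes per direction below background in 1 group, the proposed targets, and up to 4 members of each list by smallest p. For a gene not well above background on either array of a group, the change is given as a bound: the bright group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal well above background. This bound is not a minimum. It equals the plain change where the gene's own signal is the higher, and normexp gave smaller changes.

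On simulated arrays with 200 changed features among 23155, the test of miR-125a-3p against miR-neg recovered 0.152% of features changed by 0.5 on the log2 scale, 5.52% of those changed by 1 and 74.3% of those changed by 2, with 3.6 false calls per run over 10 runs. With 20% of features changed by 1, it recovered 88.3% of them, and 3.96% of its calls were false, over 5 runs. Recovery thus depended on how many features changed. Simulated variances followed the distribution that the test assumes, with normal noise and no link to signal, so a low rate of false calls was built in. On the real arrays the spread widened toward dim signals, so these rates need not hold there. The list test called a list shifted by 0.3 in 20 of 20 simulated runs and called 1 of 440 unshifted lists. Simulated genes varied independently, so these counts do not give the error rate for lists whose genes move together. The estimated correlation was 0.310 within the microglia list and 0.372 within the extracellular matrix list. The number of arrays limits the precision of every value.

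Alternatives were quantile normalization, median centring, the deposited table, no filter or a stricter filter on dim probes, the mean of a gene's probes, eBayes with a variance trend or robust, the replicate number as a block, a threshold of 0.1, and each array left out. Normexp background correction was planned on mean spot signals, which were not used here. It was run on median spot signals, with an offset of 50, as an alternative chosen after seeing the data. The planned comparison of genes with and without a seed site for the microRNA in their 3′ UTR was not run, because no UTR sequences were used here. Figures were drawn with matplotlib 3.10.9.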

Results

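Expression was measured in rat OPCs 48 h after transfection with the miR-125a-3p mimic (2 samples) or the negative control RNA (2 samples), 1 array per sample. The miR-neg arrays had 26332 and 26822 probes well above background, and the miR-125a-3p arrays had 28138 and 26902. The 75th percentile of the processed signal was 745 and 679 on the miR-neg arrays and 702 and 717 on the miR-125a-3p arrays, and 0 spots were saturated. The SD of the log2 difference between the arrays of a group was 0.34 for miR-neg and 0.33 for miR-125a-3p, against at least 0.40 for a pair of arrays from different groups.

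The comparison asks which transcripts differ when miR-125a-3p is raised in these precursors. In limma, 3 of 39 myelin genes, Adamts4, Aspa and Gpr37, fell by 1.49, 1.55 and 1.01 on the log2 scale after the mimic (SE 0.10, 0.12 and 0.09, n = 2 per group), and 2 of 19 committed precursor genes fell. Of 17 inflammatory genes, 4 rose, among them the chemokine genes Cxcl1 and Ccl2 by 2.39 and 1.94 (SE 0.09 and 0.12). Camera called these 3 lists at its preset correlation, with adjusted p-values of 0.167, 0.193 and 0.167 in the same order with an estimated correlation. The astrocyte marker Aldh1l1 rose by 1.89 (SE 0.09) and the microglial complement gene C1qa by 1.44 (SE 0.10). In limma, 159 of 23155 features passed an adjusted p of 0.05, 88 higher and 71 lower, and 62 and 43 of these had a gene symbol.

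Among genes with a symbol that passed and were well above background on all 4 arrays, the 10 with the largest decreases had adjusted p-values between 0.0333 and 0.0374 in limma. Casr, the calcium-sensing receptor, fell by 2.95 (SE 0.08), from a mean of 0.44 ± 0.01 to -2.52 ± 0.04 (SD, n = 2 each, log2 relative to the 75th percentile). Lpar1, a receptor for lysophosphatidic acid, fell by 2.28 (SE 0.14), and its second probe changed by -2.26. Slc12a7, a potassium-chloride cotransporter, fell by 2.09, and Pmp2, a lipid-binding protein of peripheral myelin, fell by 1.79. The other 6 were the myosin heavy chain gene Myh8 (-2.73), Fam163a (-2.64), Nod1 (-2.12), Lzts1 (-2.04), Fhdc1 (-1.81) and Galnt14 (-1.78). The probes of Nod1, an intracellular sensor of bacterial peptidoglycan, differed in size, with -0.29 at its second probe. Mrap2 was not well above background after the mimic and was 2.32-fold lower by the bound, which equals its plain change (adjusted p = 0.0374). Normexp background correction ended this call (log2 -0.25, adjusted p = 0.0807).

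Among genes with a symbol that passed and were well above background on all 4 arrays, the 10 with the largest increases had adjusted p-values between 0.0333 and 0.042 in limma. Gsta1, a glutathione transferase, rose by 2.43 (SE 0.19), from -0.86 ± 0.35 to 1.57 ± 0.10 (SD, n = 2 each). Ccn2, a secreted matricellular protein, rose by 2.18 (SE 0.16), and Lcn2, which binds bacterial siderophores, rose by 2.15 (SE 0.13). Mt2A, a metallothionein, rose by 1.95 (SE 0.11) from 3.39 ± 0.15 in the controls (SD, n = 2). Cxcl1, Ccl2 and Aldh1l1, given above, also belonged to this group, as did Slamf9 (1.77), the lysosomal protease gene Ctsc (1.75) and Serpinf1 (1.69). Apart from Gsta1 and Mt2A, the genes of this group were dim in the controls, with means from -4.7 (Ccn2) to -3.0 (Ccl2). Among genes not well above background in the controls, the bound was 4.16-fold higher for Tm4sf1, 3.58-fold for the urea cycle gene Ass1 and 3.46-fold for Tnfaip2. The Tm4sf1 bound equals its plain change. With normexp, the log2 changes of Tm4sf1, Ass1 and Tnfaip2 were smaller, at 0.52, 0.50 and 0.41.

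**Figure D1:**
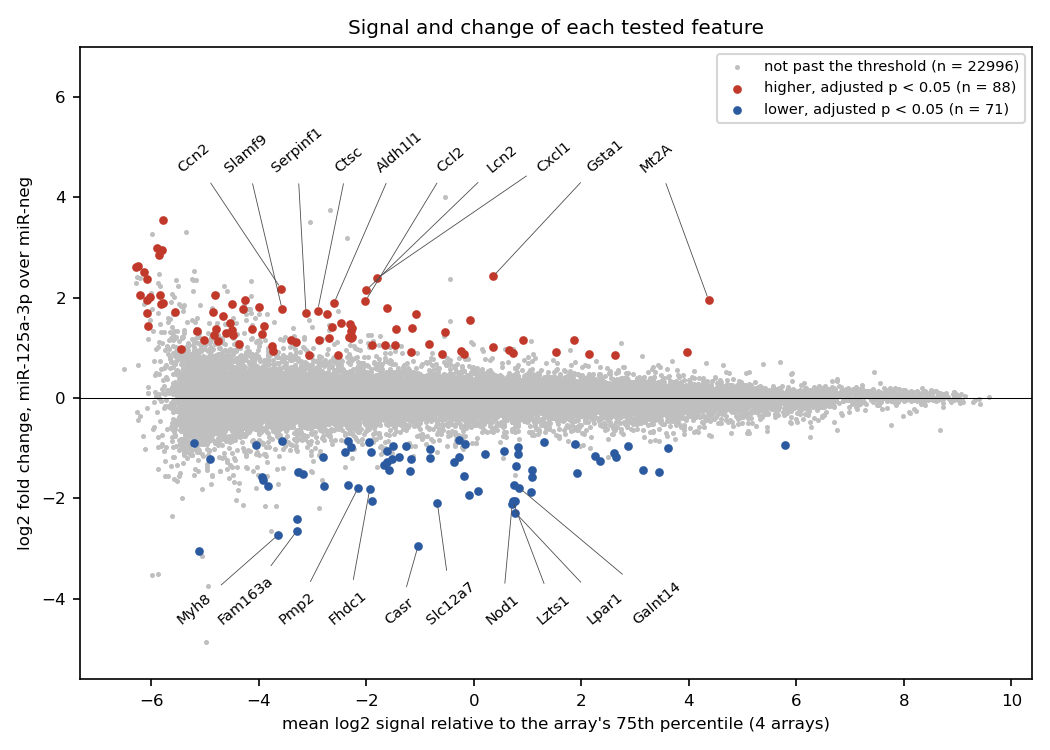
Log2 fold change of miR-125a-3p over miR-neg against mean log2 signal over the 4 arrays for 23155 features, with the 88 higher and 71 lower features past an adjusted p of 0.05 in colour. The named genes are labelled, and the spread of the grey points widens toward dim signals.

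Of 39 tested myelin and mature oligodendrocyte genes, 29 lay below 0 (median -0.26, and -0.16 with normexp). Adamts4, Aspa and Gpr37 fell, 36 did not pass, and 16 were lower and 2 higher adjusted over the list alone. Camera called the list lower (adjusted p = 1.22e-06). The call was lost with an estimated correlation (adjusted p = 0.167), although the estimate (-0.015) lay below the preset. Cldn11 (-0.69) did not pass over all genes, and Aspa's second probe changed by -0.79. Mbp (-0.64) and the transcription factor gene Myrf (-0.47), chosen after their values were seen, did not pass either (adjusted p = 0.0705 and 0.101 in limma). The second kept probe of Mbp changed by -0.31. Of 19 committed precursor genes, 15 lay below 0 (median -0.25). Cnksr3 and Parvb fell by 1.42 and 1.06, 17 did not pass, and 6 were lower and 1 higher adjusted over the list alone. Camera called this list lower (adjusted p = 0.000257), and with an estimated correlation the adjusted p was 0.193. Arpc1b (-0.99) and Mycl (-0.46) did not pass over all genes.

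OPC identity genes were not called as a list (median 0.10 over 32 genes, camera adjusted p = 0.485). None of them passed in limma over all genes or adjusted over the list alone, counts of 0 in each case with 7 at an unadjusted p under 0.05, and the smallest p-values belonged to Pdgfra (-0.37), Neu4 (0.37), Matn4 (0.39) and Kcnj10 (-0.38). Of 24 cholesterol synthesis genes, 22 lay below 0 (median -0.28), including Tm7sf2 (-0.50) and Cyp51 (-0.42). The count past the threshold was 0 in limma, also adjusted over the list alone, with 19 at an unadjusted p under 0.05. Camera called the list lower (adjusted p = 1.39e-08), and with an estimated correlation the adjusted p was 0.167.

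Of 35 S-phase and replication genes, 33 lay above 0 (median 0.26), with 0 past the threshold in limma, 5 higher adjusted over the list alone and 18 at an unadjusted p under 0.05. Among them, Tk1 was at 0.84 and Mcm2 at 0.45. Camera called the list higher (adjusted p = 2.72e-07), but the adjusted p was 0.282 with an estimated correlation. Of 36 G2/M and mitosis genes, 33 lay above 0 (median 0.23). Ccnb1, cyclin B1, rose by 1.16 (SE 0.09), 35 did not pass, and 1 passed adjusted over the list alone, while Ndc80 (0.38), Cdc20 (0.33) and Nuf2 (0.41) did not pass. Camera called the list higher (adjusted p = 2.47e-06), and with an estimated correlation the adjusted p was 0.167.

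Of 17 inflammatory cytokine and NF-kB genes, 16 lay above 0 (median 0.49). Cxcl1, Lcn2, Ccl2 and the adhesion gene Icam1 (1.05) rose, 13 did not pass, and 11 were higher adjusted over the list alone. Camera called the list higher (adjusted p = 1.12e-06), and with an estimated correlation the adjusted p was 0.167. Of 24 astrocyte markers, 22 lay above 0 (median 0.34, and 0.19 with normexp). Aldh1l1 rose, 23 did not pass, and 13 were higher adjusted over the list alone, among them Aqp4 (1.53), Apoe (1.10) and Clu (0.73). Camera gave an adjusted p of 2.47e-06 for this list, and 0.167 as the adjusted p with an estimated correlation. Of 18 microglia and macrophage markers, 13 lay above 0 (median 0.44, and 0.17 with normexp). C1qa rose, 17 did not pass, and 8 were higher adjusted over the list alone, among them Aif1 (1.56), Tyrobp (1.36) and Fcer1g (1.40). Camera gave an adjusted p of 0.000301 for these markers, and 0.551 as the adjusted p with an estimated correlation, and fry did not call them (adjusted p = 0.0868).

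Of 15 endothelial, pericyte and fibroblast markers, 12 lay above 0 (median 0.32, and 0.17 with normexp). Tagln, which encodes an actin-binding protein of smooth muscle, rose by 1.21, 14 did not pass, and 6 were higher and 1 lower adjusted over the list alone. Col3a1 (1.32), Col1a1 (1.42) and Col1a2 (0.64) did not pass over all genes. Camera gave an adjusted p of 0.00506, and 0.551 as the adjusted p with an estimated correlation, and fry gave 0.0706. Of 30 extracellular matrix genes, 19 lay above 0 (median 0.22). The collagen genes Col18a1, Col6a2 and Col11a1 rose by 1.30, 1.27 and 0.86 and the protease inhibitor gene Timp1 by 0.89, 26 did not pass, and 13 were higher and 4 lower adjusted over the list alone. Camera gave an adjusted p of 0.00984, and 0.766 as the adjusted p with an estimated correlation, and fry gave 0.0848. The call on this list also ended without miR-125a-3p replicate 2 (adjusted p = 0.0543) and on probes above background on all 4 arrays (adjusted p = 0.15). Of 21 heat shock and oxidative stress genes, 17 lay above 0 (median 0.15, and 0.09 with normexp). Mt2A and the small heat shock protein gene Hspb1 (0.93) rose, 19 did not pass, and 4 were higher adjusted over the list alone, with Srxn1 at 1.24. Camera gave an adjusted p of 0.00221, and 0.551 as the adjusted p with an estimated correlation, and fry gave 0.0571.

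**Figure D2:**
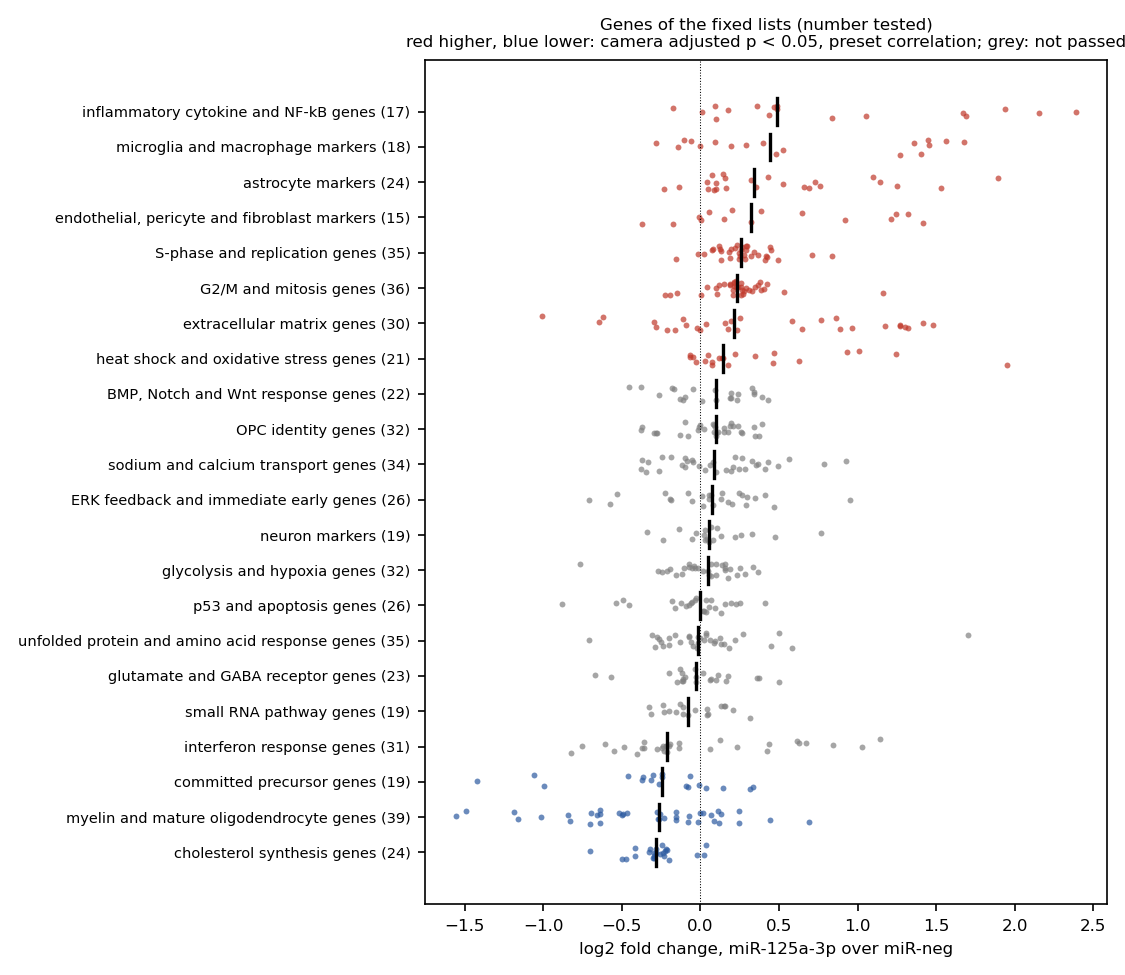
Log2 fold change of every tested member of 22 lists, 1 point per gene, with a black bar at each list's median. The 8 lists called higher are red and the 3 called lower are blue by camera at the preset correlation, and 0 lists were called with an estimated correlation, where 5 had an unadjusted p under 0.05.

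Another 11 lists, OPC identity included, were not called. Neuron markers had a median of 0.05 (camera adjusted p = 0.277), with 2 of 19 higher adjusted over the list alone, Snap25 (0.47) and Reln (0.77). Interferon response genes had a median of -0.21 and a mean of -0.03 (adjusted p = 0.485). Psmb8 (1.03), Irf1 (0.62) and Gbp2 (1.14) were the 3 members higher adjusted over the list alone. Without miR-125a-3p replicate 2, camera called this list lower (adjusted p = 0.0214). Gadd45b fell by 0.88 among p53 and apoptosis genes (median 0.00, adjusted p = 0.376), where 3 of 26 genes were lower adjusted over the list alone. Unfolded protein and amino acid response genes had a median of -0.01 and a mean of 0.04, and camera's direction was down (adjusted p = 0.731). The transsulfuration gene Cth was 1.94-fold higher by the bound, a call that normexp ended (log2 0.25, adjusted p = 0.0819), and 3 genes were higher and 1 lower adjusted over the list alone. The tropomyosin gene Tpm2 was 2.47-fold higher by the bound at the probe tested (log2 0.38 with normexp), while a second probe, well above background on 1 array, was at 1.59 and another, on 0 arrays, at -0.58.

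ERK feedback and immediate early genes had a median of 0.07 (adjusted p = 0.87), and Fos (-0.57), Jun (-0.53) and Atf3 (-0.71) were lower adjusted over the list alone. Glutamate and GABA receptor genes had a median of -0.03 (adjusted p = 0.485), with Gria2 (0.50) higher and Grik2 (-0.67) lower adjusted over the list alone. Glycolysis and hypoxia genes had a median of 0.05 (adjusted p = 0.833), with Adm (-0.76) lower adjusted over the list alone. Sodium and calcium transport genes (median 0.09, adjusted p = 0.485), BMP, Notch and Wnt response genes (median 0.10, adjusted p = 0.833) and small RNA pathway genes (median -0.08, adjusted p = 0.313) had 0 members past limma's threshold over all genes or adjusted over the list alone, with 11, 7 and 3 members at an unadjusted p under 0.05.

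Fyn, Rhoa, Mapk14 and Nrg1, proposed as targets of this microRNA before this series, were examined gene by gene. In limma, 0 of the 4 passed over all genes and 2 had an unadjusted p under 0.05. Fyn, a Src-family kinase gene, changed by -0.08 (SE 0.08, adjusted p = 0.65), and Rhoa by 0.07 (SE 0.08, adjusted p = 0.68). Mapk14, which encodes p38 alpha, changed by 0.40 (SE 0.08, adjusted p = 0.118) and the growth factor gene Nrg1 by 0.94 (SE 0.15, adjusted p = 0.0868). Nrg1's second kept probe, well above background on 3 of the 4 arrays, changed by 0.41. At the probes tested, both genes lay above 0 and both passed adjusted over the list alone (adjusted p = 0.0138 and 0.011). Slc8a3, a sodium-calcium exchanger gene, was remembered as the target the study chose from these samples, so it is not independent evidence. It was well above background on 1 of the 4 arrays and was left out of the main fit. Its signals were 24.0 and 24.7 in miR-neg, where 1 of 2 arrays was well above background, and 7.01 and 10.3 in miR-125a-3p, where 0 of 2 were. A limma fit over all probes gave -1.51 (SE 0.23, unadjusted p = 0.0041), and without the filter on dim probes 0 features passed. With the miR-125a-3p signals raised to the lowest well above background, it was 2.73-fold lower (log2 -1.45), close to the plain change of -1.51. This is not a minimum, since the controls were dim too. Of the control signals of 24.0 and 24.7, 1 was itself not well above background, so the raised level is not a detection limit for this probe. The log2 difference of Slc8a3 was -0.25 with normexp.

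**Figure D3:**
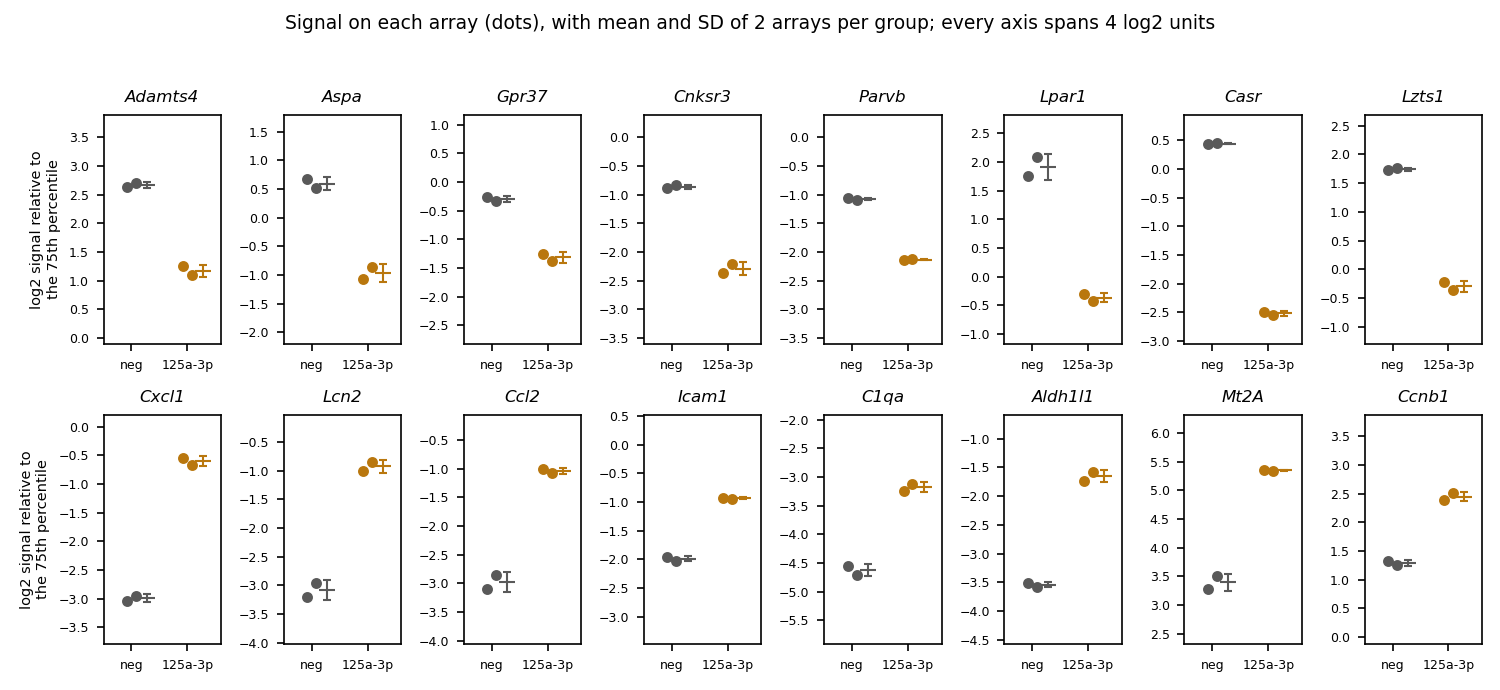
Log2 signal relative to the array's 75th percentile of 16 genes on each of the 4 arrays, as dots, with the mean and SD of 2 arrays per group beside them. In each panel both miR-125a-3p arrays lie on 1 side of both miR-neg arrays.

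The smallest adjusted p in limma was 0.0333, 4516 features had an unadjusted p under 0.05 where 1158 would by chance, and groups were separated in 52.9% of features where chance gives 33.3%. The count of 159 ranged from 0 to 2048 with the processing, was 83 (37 higher, 46 lower) under quantile normalization, which ended 14 of the 41 calls on named genes, was 0 with a block on the slide axis that the groups shared, which ended all 41 calls on named genes and none of the 11 on lists, and was 0 when any 1 of miR-neg replicates 1 and 2 and miR-125a-3p replicates 1 and 2 was left out. Normexp made 18 of these 41 changes over 1.5 times smaller and ended 2 of the calls, and a variance trend ended 1. Calls were gained too. Of the named genes not called in the main fit, 57 passed with normexp and 59 with a variance trend. On probes above background on all 4 arrays, 25 did. A gene said not to pass therefore did not pass in the main fit. All 4 arrays came from 1 slide and 1 scan. The position of an array along 1 axis of the slide followed its group, so position and group cannot be told apart.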

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

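Normexp on median spot signals and all features as the background of camera were chosen after seeing the data. The count of 159 features (88 higher, 71 lower) became 83 (37 and 46) under quantile normalization, 613 (283 and 330) on probes above background on all 4 arrays, 2048 (1017 and 1031) with a variance trend, 1648 (806 and 842) with normexp and 984 (514 and 470) at a threshold of 0.1. It stayed between 142 and 164 with median centring, the deposited table, the mean of probes and robust variances. It was 0 (0 and 0) without a filter on dim probes, where limma's unadjusted p was under 0.05 for 3956 features, and it ranged from 0 to 0 with 1 array left out, with 2748 to 4116 such features. A lone array is then assumed to vary like the other group. With the replicate number as a block, the same as a block on the other slide axis, the count was also 0 (0 higher, 0 lower), with 3968 such features and a smallest adjusted p of 0.0641. Same-numbered arrays had deviations correlated at 0.0505 over features. With 2 arrays per group both pairs give the same value, so it cannot decide whether the numbers pair the samples. The main fit, fixed beforehand, did not pair them, although same-numbered arrays also shared a position on that axis. The cause of these shifts was not tested. All 159 kept their direction in each setting that measured them, except Tpm2 without the filter (-0.58), where a brighter probe, not well above background, stood for it. Of the 24 called genes that the rule named by size, among those well above background on all 4 arrays or below it in 1 group, 19 passed under quantile normalization (highest adjusted p 0.0613), 23 with normexp (0.0807, Mrap2), 0 with the block (0.0786) and 23 with the mean of probes, where Nod1 did not (-1.21, adjusted p = 0.166).

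Camera called 11 lists at the preset correlation in each setting but 1, with 10 on probes above background on all 4 arrays. They were the same 11 lists, except that without miR-125a-3p replicate 2 the interferon list took the place of the extracellular matrix list. Fry called 7, without the microglia, extracellular matrix, endothelial and heat shock lists, and the estimated correlation 0, with 5 at an unadjusted p under 0.05. The estimate lay below the preset 0.01 for the cholesterol (-0.038), committed precursor (-0.038), inflammatory (-0.022), myelin (-0.015), astrocyte (-0.013) and G2/M (0.008) lists. The estimated correlation therefore did not cause the loss of those calls in that repeat. The estimates rest on 2 residual degrees of freedom, so they do not exclude correlation between the genes of those lists. For the other called lists it lay between 0.092 and 0.372. The 11 kept their direction throughout. Of the targets, 1 passed on probes above background on all 4 arrays (Nrg1), 2 with a variance trend (Nrg1 and Mapk14) and 1 with normexp (Mapk14), all above 0. Slc8a3, left out of the main fit as too dim, was at -0.25 with normexp. Lists that were not called changed the direction of their test, which can differ from the sign of the median given here. Unfolded protein genes were at -0.0145 without the filter and with fry, ERK feedback genes at 0.0743 and interferon genes at -0.21 with fry. With 1 array left out, the medians ranged from 0.000467 to 0.0968 for BMP, Notch and Wnt genes, 0.00652 to 0.13 for ERK feedback genes, 0.00712 to 0.082 for glycolysis genes and -0.322 to -0.0303 for interferon genes. Genes near 0 changed sign too. P2ry12 was at 0.000628 under quantile normalization and 0.0436 with normexp. With 1 array left out it ranged from -0.0618 to 0.0603, S100b from -0.0437 to 0.13, Itgam from -0.0762 to 0.265, Olig2 from -0.0885 to 0.0591 and Cx3cr1 from -0.14 to 0.0158. The seed-site comparison, normexp on mean signals, a slide block (1 slide) and robust variances for camera, which has no such option, were not run.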

Other observations

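The tests of unchanged microglia and of unchanged astrocytes, and the comparisons of dim markers and with normexp, were chosen only after the results were seen. So were the genes named here outside the naming rule. Related genes differed in size. Mt2A rose by 1.95, while Mt3 changed by 0.69 (adjusted p = 0.0879) and Mt1 by -0.05 (adjusted p = 0.777). Myh8 fell by 2.73, and Myh1 changed by -2.04 without passing limma's threshold (adjusted p = 0.0524). Lpar1 fell by 2.28, and Lpar4 changed by 0.30 (adjusted p = 0.488). The lineage factor genes Sox10 (-0.08), Olig1 (0.18) and Olig2 (-0.01) had adjusted p-values of 0.642, 0.496 and 0.948 in limma. The division marker Mki67 was at 0.22 (adjusted p = 0.299). Within the interferon list, Isg15 (-0.76), Usp18 (-0.82) and Oas1a (-0.61) lay below 0 and Psmb8 and Gbp2 above it, and the estimated correlation within the list was 0.775.

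Myelin genes were lower after miR-125a-3p, with 3 of 39 past limma's threshold and a camera call lost with an estimated correlation (adjusted p = 0.167). An even loss of cells across the oligodendrocyte lineage would lower OPC identity genes too, but their median lay 0.358 above that of myelin genes on the log2 scale (95% bootstrap interval over genes 0.178 to 0.641, 32 and 39 genes) and 0.239 above it with normexp (0.127 to 0.555). Intervals over genes, here and below, do not measure the spread between samples. Of the 32 OPC identity genes, 21 lay above 0 and 11 below, and 8 also belonged to another list. Whether other cells supplied part of their signal was not tested, so an even loss is not excluded. The comparison does not bear on a loss of only some cells of the lineage. Scaling and background correction do not account for all of it, since under quantile normalization, median centring and normexp the list stayed lower with an adjusted p of at most 1.98e-06 in camera at the preset correlation, although its median went from -0.26 to -0.16 with normexp. Position on the slide cannot be told apart from the group, because 0 positions along the axis that differs held both groups. A change in gene expression within the cells was not tested.

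Astrocyte and microglia markers were called higher by camera after miR-125a-3p, with 1 of 24 and 1 of 18 past limma's threshold and both calls lost with an estimated correlation (adjusted p = 0.167 and 0.551), and with fry not calling the microglia markers (adjusted p = 0.0868). A smaller share of lineage cells would raise markers of every other cell type present alike, if those cells supplied the signal. The astrocyte and microglia markers had a median 0.326 above that of neuron markers (95% bootstrap interval over genes 0.0707 to 0.624, 42 and 19 genes). The difference was 0.578 among markers dim in the controls (0.266 to 1.28, 26 and 9 genes) and 0.163 with normexp (0.0318 to 0.341). Whether neurons supplied the neuron-marker signal was not tested. Some of these markers, such as Gap43 (4.43), Dcx (3.20) and Elavl3 (3.04), were bright in the controls. The comparison therefore cannot decide whether the share of lineage cells fell. The endothelial, pericyte and fibroblast list was called higher (median 0.32, adjusted p = 0.551 with an estimated correlation), but its 5 endothelial members lay between -0.18 (Kdr) and 0.20 (Vwf), and Col1a1 was at 1.42. More microglia or more astrocytes of unchanged state may still account for part of it, although markers dim in the controls did not share 1 factor. The simulated p was 3e-04 over 10 microglia markers, where Aif1 was at 1.56, Itgam at 0.09 and Spi1 at -0.14. It was 1e-05, the smallest the simulations can give, over 11 astrocyte markers, where Gja1 was at 1.25, Slc1a2 at 0.05 and Bmpr1b at -0.23. Part of a marker's signal can come from other cells, and 0 markers were lower adjusted over the list alone. The bright markers P2ry12 (0.00, of either sign by scaling), Cx3cr1 (-0.06) and S100b (0.04) would hide a small share. Brightness does not account for Spi1 and Tmem119 (-0.10), with control means of -4.73 and -5.08, while C1qa rose from -4.63. Tmem119 was well above background on only 1 control array. These 2 explanations stay open, like a smaller share of lineage cells, slide position and a response of the cells already present.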
